A study of Drosophila melanogaster with 16 samples.

How the data were processed

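The study made ATAC-seq libraries with the Omni-ATAC variant of the protocol, which lowers the share of mitochondrial reads, from fat body dissected from Drosophila melanogaster females. There were 16 libraries in 4 groups of 4, and each group is a temperature, 25 °C or 11 °C, with ethanol or S-methoprene. Per the labels' protocols, ethanol of 99% or 39.4 mM S-methoprene in it was given as vapour, 10 µL every 2 days, and flies were put into their condition soon after eclosion for 25 days. Replicates are numbered in the labels, and nothing states that a number marks a shared batch.

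Per the submitters' processing notes, FastQC, Trim Galore, cutadapt, Bowtie2, SAMtools, Picard, MACS2, bedtools and DiffBind were used, without versions, roles or order, and the genome build was dm6. Whether reads were shifted for the transposase offset, how duplicates and multiply mapped reads were treated, how the peak set was made and how libraries were scaled is not given in the sources used here. These steps can change the values: multiply mapped reads matter at repeated genes such as tRNA genes, and scaling on all reads or on reads in peaks can shift all fold changes by one factor.

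A single file was analysed, the authors' deposited table of the temperature comparison. Per the file headers it holds, for each of 8069 peaks, the log2 mean concentration over all libraries used, over the 25 °C libraries and over the 11 °C libraries, where the concentration is a number of normalised reads in the peak. It also holds the authors' log2 fold change and the deposited p-value with its FDR. The table was checked before use. The sign of the fold change goes with the 25 °C minus the 11 °C concentration in all but 256 peaks, none of which was called. The FDR equals a Benjamini-Hochberg adjustment of the 8069 p-values to within 1.78e-15. The deposited fold changes have a slope of 0.805 on the difference of concentrations, so they are smaller than that difference. In 3446 peaks whose concentrations differ by over 0.2 (log2), the overall mean is the mean of both temperatures with a weight of 0.429 on 25 °C, within a tolerance of 1e-06. With up to 8 libraries per temperature only 3 against 4 and 6 against 8 libraries give that weight. The labels list 8 per temperature, so at least 2 of the 25 °C libraries did not enter, and which did is not stated. In 16 peaks both concentrations are 0, and 1 peak has a start below 1, all kept as listed. Depth per library is unknown, so no interval or floor on read numbers is given.

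Because the table holds no value per library, no model was refitted. A peak was called when its FDR was under 0.05, and split by the sign of its fold change. The design fixed before the data were examined was followed where the data allowed. Gene positions came from a RefSeq gene table of the Release 6 plus ISO1 MT assembly, on which dm6 is based, with 17807 genes on the chromosomes used. It gives the start and end of each gene without strand, exons or sequence. The planned classes by transcription start, exon and intron were therefore replaced by gene end (peak midpoint within 500 bp of either end of a gene), gene body and intergenic. A peak was assigned to each gene that contains its midpoint or has an end within 1000 bp of it, and otherwise to the gene with the nearest end (275 peaks). In this way 9474 genes had a peak and 4637 peaks had several genes, so a peak counted for a gene is not shown to regulate it. Where 1 gene had to be named for a peak, a protein-coding gene went first, then the nearest end. Sequence motifs and GC content need the genome sequence and were not analysed here, and peak width was constant but for 3 peaks.

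The tests are two-sided Fisher's exact tests of shares, permutation tests of differences of medians with 100000 resamples, permutations of signs (10000) for neighbouring peaks and for genes with both directions, and random lists (10000) matched on the number of peaks per gene, with genes of 12 or more peaks pooled. Benjamini-Hochberg adjustment was made within each family. P-values over peaks or genes describe this table, and peaks and genes are not replicates. The 22 gene lists were fixed before the data were examined. Of their 631 entries 585 matched a gene symbol, 28 a synonym and 18 no gene. A few genes stand in 2 lists (apolpp, eloF and sgg among them), and an entry for a fat body protein was matched by synonym to fbp, an enzyme of sugar synthesis. Named peaks were chosen by a rule fixed at the same time: the 10 most changed called peaks in each direction, the 2 most changed in each direction of each list (the text gives at least the first), and 15 genes named whatever their values (Kr-h1, Met, gce, foxo, InR, Ilp6, Thor, bmm, Yp1, Yp2, Yp3, EcR, Hr38, Clk and Trl). Genes named outside it are said to be so.

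The tests were tested on simulated data. With calls permuted among the 8069 peaks within location classes, Fisher's exact test of gene lists on 9474 genes made a mean of 2.35 calls of 44 and at least 1 in 87 of 100 permutations, while matched random lists made 0 in 10 permutations. A planted list of 30 genes was recovered in 20 of 20 runs by each test. For Fisher's exact test this was by the adjusted p, and for random lists by the p of that list alone, without adjustment. On the 1789 called peaks the permutation test of medians called 1 of 40 null data sets and 40 of 40 with a planted shift, and the neighbour test 1 of 20 and 20 of 20. Location tests made a call in 5 of 100 permutations. Draws matched on location and concentration called 7 of 200 random sets of 60 peaks.

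Alternatives tried were FDR limits of 0.01, 0.001 and 0.1, a minimum log2 fold change of 1, subsets of chromosomes, leaving out the lowest of 4 concentration bins, centring of fold changes, other gene-end windows and assignments, and protein-coding genes alone. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.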

Results

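Chromatin accessibility was measured by ATAC-seq in the fat body of adult Drosophila melanogaster females. ATAC-seq uses a transposase to cut open chromatin, so that the number of reads in a peak measures how accessible that stretch of DNA is. The fat body is the fly's main organ of lipid and glycogen storage and also secretes yolk proteins and antimicrobial peptides. The flies were w1118 virgins held for 25 days either at 25 °C or at 11 °C, a temperature at which adult females enter a reproductive arrest called diapause. At each temperature the flies received volatilised ethanol as vehicle or S-methoprene, a synthetic analog of juvenile hormone, which gives 4 groups of 4 libraries and 16 libraries in all. Each library was made from 25 flies, and these were picked by the look of their ovaries. At 11 °C with ethanol the ovaries were regressed, and in the other 3 groups they were large. Ovary state is therefore part of how the samples were chosen and not an outcome.

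The comparison analysed here is that of 25 °C with 11 °C, as given in the authors' deposited table of differential accessibility on the dm6 build. It lists 8069 peaks, of which 8066 are 401 bp wide, each with a mean normalised read number per temperature, a fitted log2 fold change and a false discovery rate (FDR). Fold changes below are 25 °C over 11 °C, and all are the authors' fitted values. No value per library was analysed, so the depth of each library is unknown, no standard error accompanies a fold change, and ethanol and S-methoprene flies were not compared here. In the authors' deposited table the overall mean of each peak weighs the 25 °C libraries against the 11 °C libraries as 3 to 4, which 3 against 4 or 6 against 8 libraries would give. Which libraries and which drug groups those were is not stated, so the difference below is between temperatures with the drug unresolved. Flies at 25 °C were all picked with large ovaries, and those at 11 °C with ethanol with regressed ones. Temperature and ovary state therefore go together in part or in full, and cannot be told apart here. The median peak held 163 normalised reads, with quartiles of 97.4 and 257.

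The comparison asks where fat body chromatin differs between the warm and the cold condition. Accessibility was higher at 25 °C at 6 of the 7 peaks assigned to the lipid carrier gene apolpp, by up to 5.05-fold. It was also higher at 15 of 36 genes of humoral immunity, and 6 of the 36 had a peak higher at 11 °C. The immunity call passed against random lists matched on peaks per gene but not against draws matched on location and concentration (permutation tests, adjusted p = 0.0088 and 0.0682). Accessibility was higher at 11 °C at the single peak of the insulin-like peptide gene Ilp6. By the authors' deposited table, 981 peaks were more accessible at 25 °C and 808 at 11 °C at an FDR under 0.05, together 22.2% of all peaks. The median called peak was 1.43-fold higher at 25 °C or 1.31-fold higher at 11 °C. Changes of at least 2-fold numbered 124 at 25 °C and 51 at 11 °C. The median log2 fold change over all peaks was -0.0029, with quartiles of -0.09 and 0.09, so calls lay on both sides of a centre near 0. The direction of the majority depended on weak peaks. With the peaks split into 4 bins by read concentration, 489 of the lowest bin were higher at 25 °C and 158 at 11 °C, and of the highest bin 78 and 257. Without the lowest bin, 492 peaks were higher at 25 °C and 651 at 11 °C, so the share of calls that were higher at 25 °C went from 54.8% to 43.0%. Among calls of at least 2-fold that share was 70.9%.

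**Figure D1:**
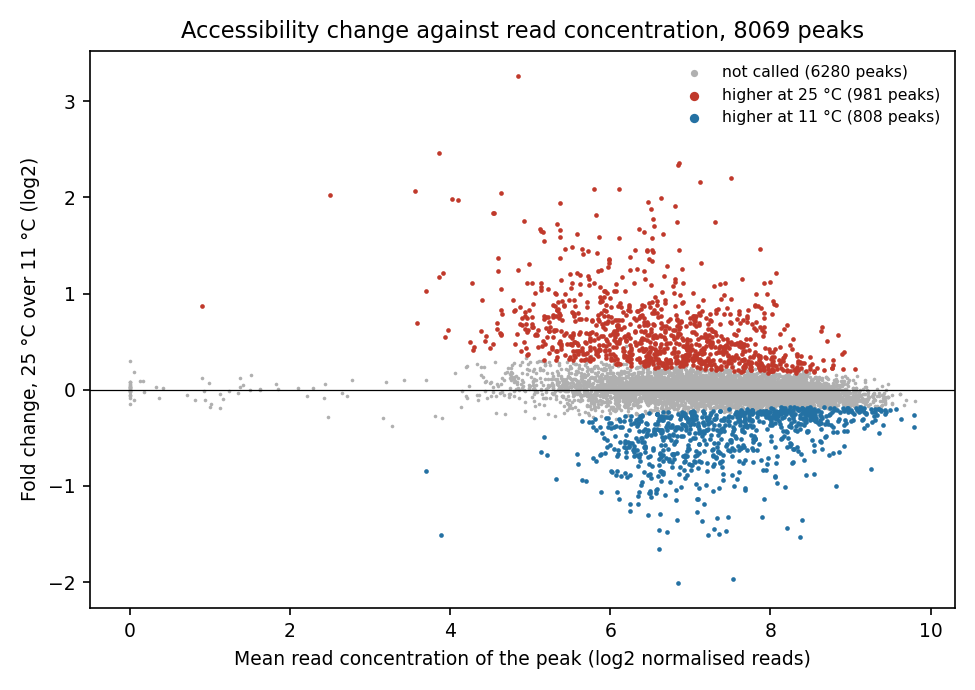
Each point is 1 of the 8069 peaks, with its mean read concentration on the x axis (log2 normalised reads) and its log2 fold change, 25 °C over 11 °C, on the y axis. The 981 peaks higher at 25 °C are red (489 of them in the lowest of 4 concentration bins), the 808 higher at 11 °C are blue, and peaks not called are grey.

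Among genes with several changed peaks, large changes lay at apolpp, which encodes apolipophorin, the fat body's secreted lipid carrier protein. The authors' deposited table lists 7 peaks at this gene on chromosome 4 (1060969 to 1077273), and 6 of them were higher at 25 °C. Its most changed peak, at 1071798 to 1072198 within the gene, had a log2 fold change of 2.34 (5.05-fold, FDR 5.17e-38) in the authors' deposited table, and the next, at 1070838 to 1071238, had 2.16 (4.47-fold, FDR 4.83e-12). The other 4 called peaks had log2 fold changes of 0.35 to 1.95 in the authors' deposited table, and the peak across the gene's lower coordinate end had 0.01 (FDR 0.936). The peaks with 0.35 and 0.01 also lie within the overlapping gene Zyx, and the peak with 1.95 lies near the gene Actbeta.

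**Figure D2:**
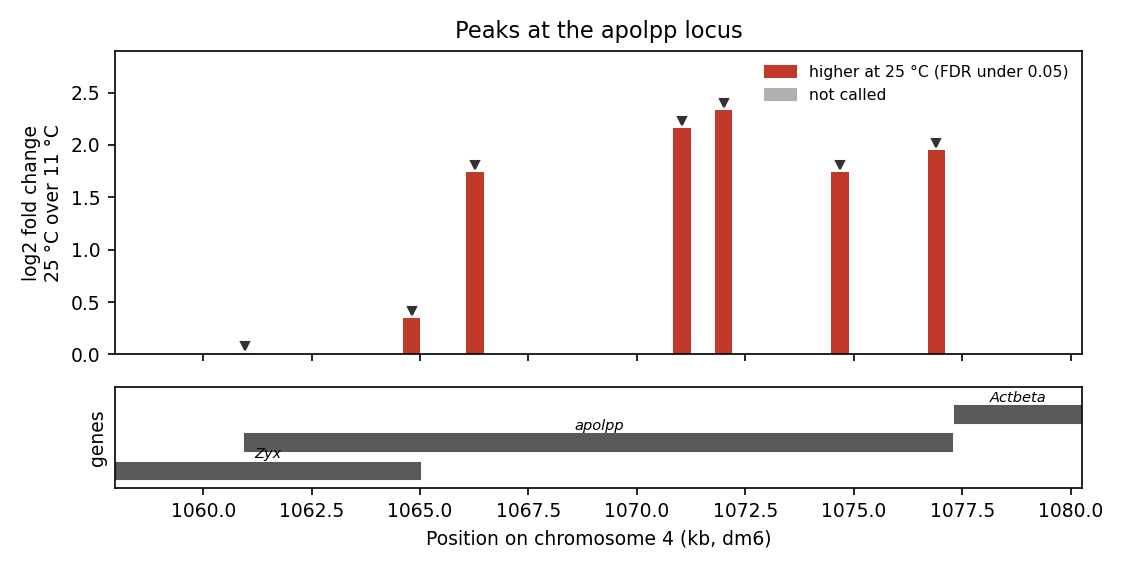
The upper panel shows the log2 fold change, 25 °C over 11 °C, of each peak along chromosome 4 (dm6, kb), drawn to its width, in red where the FDR was under 0.05, with a triangle above each bar. The lower panel shows the genes of the reference, and 6 of the 7 peaks at apolpp are red, up to a log2 fold change of 2.34, while the peak across its lower end, at 0.01, is too low for its grey bar to show.

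Outside apolpp, the most changed peaks lay at genes of several kinds. In the authors' deposited table the 2 largest increases at 25 °C, with log2 fold changes of 3.26 and 2.46, were intergenic peaks of chromosome arm 3R at 3975095 to 3975495 and 4031729 to 4032129. Their nearest gene, CG42402, lies 102644 and 46010 bp away, so the gene name only marks the place. The authors' deposited table gives a log2 fold change of 2.36 for a peak at the gene end of ppk30 (3R, 29671217 to 29671617), which encodes a sodium channel subunit and has the odorant binding protein gene Obp99a beside it. A peak 191 bp outside CG9338 (2L, 20864824 to 20865224) had 2.20 in the authors' deposited table. Within gene bodies, the authors' deposited table gives 2.08 for Ac76E, an adenylate cyclase, 2.08 for eIF4G1, a translation initiation factor, 2.06 for CG40470 and 2.05 for lovit. Both peaks near CG42402 and those in CG40470 and lovit lie in pericentromeric windows, which were chosen after the data were seen. The peak in eIF4G1, like apolpp, lies on chromosome 4. Reads at 11 °C were few: 5.52 and 4.22 near CG42402, 3.95 in CG40470 and 10.2 in lovit, against 163 in the median peak.

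The largest changes in the other direction were smaller. In the authors' deposited table the peak most in favour of 11 °C, with a log2 fold change of -2.003, lay between genes on 3R at 29206957 to 29207357, 3024 bp from Cyt-c1L. Next came -1.97 for a peak 153 bp outside Msr-110 (3L, 5577301 to 5577701), -1.66 within Pura and -1.54 near lncRNA:CR45251, again from the authors' deposited table. Peaks within Dop1R2, a dopamine receptor gene, and nAChRalpha4, a nicotinic acetylcholine receptor subunit gene, had -1.51 and -1.48 in the authors' deposited table. The Dop1R2 peak held few reads, 5.66 at 25 °C and 21.6 at 11 °C. The remaining 4 of the 10 largest, within CG10011, CG9886, Srpk79D and CG8008, had -1.51, -1.50, -1.46 and -1.46 there.

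Changed peaks lay away from gene ends. The midpoint was within 500 bp of a gene end for 42.0% of the 981 peaks higher at 25 °C and 45.3% of the 808 higher at 11 °C, against 68.5% of the 6280 peaks not called (Fisher's exact test, two-sided, adjusted p = 6.14e-55 and 1.44e-36 over 9 tests). Gene bodies held 48.8% and 47.3% against 27.8% (Fisher's exact test, adjusted p = 5.40e-37 and 1.24e-27), and intergenic stretches 9.17% and 7.43% against 3.71% (adjusted p = 5.17e-12 and 7.34e-06). Peaks higher at 25 °C and at 11 °C did not differ past the threshold in any of the 3 classes (Fisher's exact test, adjusted p = 0.212, 0.537 and 0.224), although for gene ends they did with a window of 1000 bp or with protein-coding genes alone (adjusted p = 0.0224 and 0.0124). The median distance to the nearest gene end was 1057 bp for peaks higher at 25 °C, 759 bp for those higher at 11 °C and 123 bp for the rest. Each of the first 2 differed from the rest by a permutation test of medians (adjusted p = 1.5e-05, from the smallest p that 100000 resamples can give). The 25 °C and 11 °C peaks differed from each other with adjusted p = 0.0444 by the permutation test, a call lost with peaks at an FDR under 0.01 (adjusted p = 0.0647). Median log2 concentration was 6.62 for peaks higher at 25 °C, 7.41 for those higher at 11 °C and 7.44 for the rest (permutation test, adjusted p = 1.5e-05 for 25 °C against either, and 0.613 for 11 °C against the rest).

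No chromosome arm held more or fewer changed peaks than the rest past the adjusted threshold in 18 Fisher tests. The closest was chromosome 4, the small chromosome that carries apolpp, with 18 peaks higher at 25 °C and 3 at 11 °C (Fisher's exact test, adjusted p = 0.0665).

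Neighbouring changed peaks tended to share a direction. Of 1783 pairs of changed peaks next to each other on an arm, 57.5% had the same sign, against a mean of 50.8% when signs were permuted within arms (p = 0.0002, two-sided permutation test, the smallest that 10000 permutations can give). Among the 188 pairs under 5 kb apart it was 75%, against 51.4% (permutation test, p = 0.0002). Genes with peaks in both directions were fewer than with permuted signs, 123 against a mean of 188 (permutation test, p = 0.0002). EcR, the ecdysone receptor gene, held both directions, with 4 peaks higher at 25 °C and 3 higher at 11 °C of 14.

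The genes were grouped in 22 lists, 14 of pathways and 8 of cell type markers. For each list and direction, the genes with a changed peak were counted and set against the other genes with a peak by Fisher's exact test, 44 tests in all. A gene with many peaks has more chances to hold a changed one, and this test does not allow for it. With the calls permuted among peaks of the same location class it made 2.35 calls per permutation on average and at least 1 in 87 of 100, with a highest number of 6. On the real calls it made 7. Random lists matched on the number of peaks per gene are therefore set beside Fisher's exact test. They gave no call in 10 such permutations, but with too few lists drawn for a lone call to pass over the 44 tests. How often they make a lone false call was therefore not measured. Because read concentration also differed between the calls, each list's peaks were further set against peaks drawn with the same location class and concentration decile, a test added after seeing the data.

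**Figure D3:**
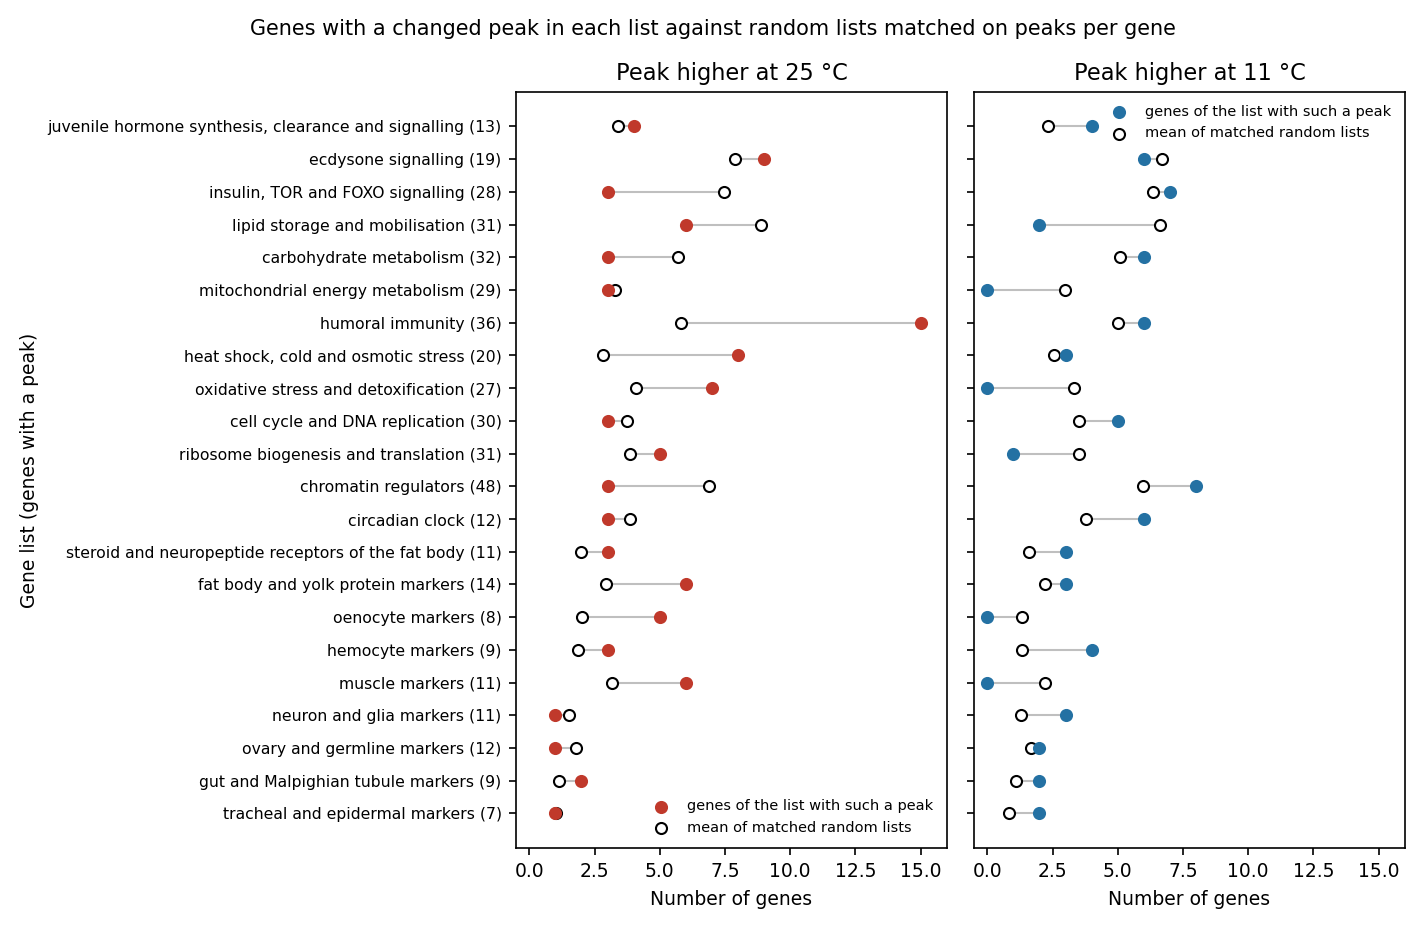
For each of the 22 gene lists (number of genes with a peak in brackets), filled points give the number of genes with at least 1 peak higher at 25 °C (left) or at 11 °C (right), and open points the mean of 10000 random lists matched on the number of peaks per gene. The difference in number of genes is largest for humoral immunity on the left, with 15 genes against a random mean of 5.82.

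Humoral immunity was the list whose gene count for 25 °C passed against random lists matched on peaks per gene. Of its 36 genes with a peak, 15 had one higher at 25 °C and 6 one higher at 11 °C, and random lists matched on peaks per gene held a mean of 5.82 for 25 °C (permutation test, adjusted p = 0.0088). Fisher's exact test gave adjusted p = 0.000767, and draws matched on location and concentration gave adjusted p = 0.0682, past the threshold no longer. Of its 61 peaks, 16 were higher at 25 °C and 5 at 11 °C, or 16 and 6 adjusted over the list alone. The authors' deposited table gives a log2 fold change of 0.82 at Stat92E, the fly's STAT transcription factor, for a peak that also lies near MtnD and MtnE, and 0.79 at dl, the NF-kappaB factor Dorsal. Further members, named after their values were seen, are the Toll receptor gene Tl with 0.79, the Toll ligand gene spz with 0.73 and -0.22, and TotA with 0.74 in the authors' deposited table. The antimicrobial peptide genes Mtk, AttC and AttD, also named after their values were seen, had log2 fold changes of 0.40, 0.28 and 0.62 in the authors' deposited table, the peak of AttD lying beside 2 tRNA genes. A peak shared by BomS2 and BomS3, immune peptide genes named in the same way, went the other way, with -0.23 (FDR 0.0352) in the authors' deposited table. Socs36E, an inhibitor of JAK/STAT signalling, held changes both ways in the authors' deposited table, -1.14 (FDR 2.73e-11) and 0.44. The peptidoglycan recognition gene PGRP-LB had -0.48 there.

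Markers of the fat body itself and its yolk proteins were higher at 25 °C in part. Of 14 genes with a peak, 6 had one higher at 25 °C and 3 one higher at 11 °C, which is 11 and 3 of 29 peaks, or 12 and 5 adjusted over the list alone. Fisher's exact test gave adjusted p = 0.035 for 25 °C. Random lists matched on peaks per gene ended that call (adjusted p = 0.293), and draws matched on location and concentration kept it (adjusted p = 0.0264). Of the 11 peaks, 6 are those of apolpp. Peaks beside the yolk protein genes Yp1 and Yp3 had log2 fold changes of 0.57 (FDR 0.0123) and 0.61 (FDR 0.0142) in the authors' deposited table. That of Yp2 had 0.37, with an FDR of 0.0794, and was not called. The fitted values are smaller than the differences of mean normalised reads in the authors' deposited table, most so for Yp2, with 477 reads at 25 °C and 203 at 11 °C, against 613 and 341 for Yp1 and 556 and 278 for Yp3. Lsp1beta, a larval storage protein gene, and srp, a GATA factor of the fat body, had -0.68 and -0.32 in the authors' deposited table, the former peak lying also near snRNA:U1:21D.

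The list of lipid storage and mobilisation passed no test, and 6 of its 13 peaks higher at 25 °C are those of apolpp. Of its 82 peaks 13 were higher at 25 °C and 2 at 11 °C, or 13 and 1 adjusted over the list alone. On genes it was 6 and 2 of 31 (Fisher's exact test, adjusted p = 0.443 and 0.759), and the balance of directions against other called peaks had adjusted p = 0.0723, so neither passed. For the peaks higher at 11 °C, the authors' deposited table gives -0.36 at mdy, a diacylglycerol acyltransferase gene, and -0.23 at the perilipin gene Lsd-2. None of the 5 peaks of bmm, the main triglyceride lipase, was called (smallest FDR 0.113).

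Insulin and TOR genes had a list median below 0. The list's median of mean log2 fold changes per gene was -0.08, at percentile 0.02 of 10000 matched random lists (permutation test, adjusted p = 0.0066 over 22 lists). With the median fold change of each concentration decile subtracted it was -0.06 (permutation test, adjusted p = 0.0581), past the threshold no longer. Of 79 peaks 3 were higher at 25 °C and 12 at 11 °C, or 3 and 10 adjusted over the list alone, a balance with adjusted p = 0.0537 by Fisher's exact test. On genes it was 3 and 7 of 28 (Fisher's exact test, adjusted p = 1 and 0.149). The numbers for 11 °C were close to those of matched random lists, 6.36 genes, and matched draws, 10.4 peaks, and those for 25 °C lay below them, 7.46 genes and 9.28 peaks, without passing (permutation tests, adjusted p = 0.293 and 0.150). The single peak of Ilp6, an insulin-like peptide gene of the fat body, had -0.63 (FDR 0.000151) in the authors' deposited table, at X 2334221 to 2334621, and it lies within reach of Raf as well. The kinase gene sgg had -0.69 and -0.64 there, while Ilp8 had 0.78 and the insulin receptor gene InR 0.48 at 1 of its 6 peaks, all from the authors' deposited table. None of the 9 peaks of foxo (smallest FDR 0.0581) and not the peak of its target Thor (FDR 0.671) was called.

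Genes of juvenile hormone, the hormone that S-methoprene mimics, showed small changes in both directions. Of 32 peaks at 13 genes 4 were higher at 25 °C and 6 at 11 °C, and as many adjusted over the list alone, with 4 genes each way (Fisher's exact test, adjusted p = 0.225 and 0.207). Kr-h1, a target gene of the hormone, held a peak with a log2 fold change of 0.49 and another with -0.23 in the authors' deposited table. The receptor gene gce had -0.26 and -0.22 at 2 of its 6 peaks there, and none of the 3 peaks of its paralog Met was called (smallest FDR 0.216). JhI-21 had 0.45 in the authors' deposited table, at a peak that also lies near CG34164 and RpL7-like. Ptth had -0.33 there, at a peak that also lies near Pph13. Ptth counts in this list although it encodes the prothoracicotropic hormone and is not itself a juvenile hormone gene.

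Ecdysone signalling held many changed peaks in both directions. Of 99 peaks at 19 genes 18 were higher at 25 °C and 12 at 11 °C, or 21 and 13 adjusted over the list alone, and 9 and 6 genes had one. Fisher's exact test gave adjusted p = 0.00601 for 25 °C, and both other tests ended that call (adjusted p = 1 for random lists matched on peaks per gene and 0.701 for draws matched on location and concentration). From the authors' deposited table, br had 0.97, Eip93F 0.92 and -0.64, and Hr3 -0.87. EcR, with 14 peaks, had log2 fold changes from -0.43 to 0.92 in the authors' deposited table, and 3 of its 4 peaks higher at 25 °C lie beside tRNA genes within its span. Hr38 had 0.22 at 1 of 2 peaks there.

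Clock genes were also split. Of 12 genes with a peak, 6 had one higher at 11 °C and 3 one higher at 25 °C. For 11 °C Fisher's exact test gave adjusted p = 0.0127, and both other tests ended that call (adjusted p = 0.563 and 1). Of 50 peaks 8 went each way, or 8 and 10 adjusted over the list alone. Pdp1, a transcription factor of the clock, holds 5 of the peaks higher at 25 °C, and sgg 3 of those higher at 11 °C. In the authors' deposited table Pdp1 had 1.45 and 1.004 at the 2 most changed of its 18 peaks, 1 of which was higher at 11 °C. Clk had 0.58 (FDR 0.000176) at 1 of its 3 peaks there. The repressor genes per and tim, named after their values were seen, had -0.53 and -0.48 in the authors' deposited table.

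Single peaks at stress genes were among the larger increases at 25 °C. The list of heat shock, cold and osmotic stress had a median of 0.0004, at percentile 55.74 of matched random lists. In the list of heat shock, cold and osmotic stress 8 of 20 genes had a peak higher at 25 °C and 3 one higher at 11 °C. For 25 °C Fisher's exact test gave adjusted p = 0.017, and the other tests ended that call (adjusted p = 0.132 and 0.397). Some of these genes share a peak, so 6 and 4 of 31 peaks were called, or 7 and 6 adjusted over the list alone. The authors' deposited table gives 1.58 (FDR 2.73e-24) for a peak 1000 bp from Hsp68, which is near Pisd and CG6000 as well, 0.77 for smp-30 and -0.43 for regucalcin. Of the 44 peaks of oxidative stress and detoxification 9 were higher at 25 °C and 0 at 11 °C, and as many adjusted over the list alone, a balance with adjusted p = 0.0537 by Fisher's exact test. On genes it was 7 and 0 of 27 (Fisher's exact test, adjusted p = 0.225 both). Among them Mdr50, a drug efflux pump gene, had 1.64 and cnc, the fly's Nrf2 gene, 1.15 in the authors' deposited table.

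Cell cycle genes had a list median of -0.06 (permutation test against matched random lists, adjusted p = 0.0477), which with the decile medians subtracted was -0.02 (adjusted p = 0.488). Of 43 peaks 3 were higher at 25 °C and 5 at 11 °C, and as many adjusted over the list alone, with 3 and 5 of 30 genes (Fisher's exact test, adjusted p = 0.893 and 0.540). E2f1, an activator of S phase genes, had 1.35 and RnrS 0.74 in the authors' deposited table, while the mitotic genes BubR1, in a peak shared with mle, and CycB3 had -0.72 and -0.71. Ribosome and translation genes had 7 peaks higher at 25 °C and 1 at 11 °C of 43, and as many adjusted over the list alone (5 and 1 of 31 genes, Fisher's exact test, adjusted p = 0.759 and 0.434). That one peak, with -1.27 in the authors' deposited table, is intergenic and 2976 bp from Tif-IA, and RpL10 had 0.78. Chromatin regulators had 4 and 10 of 75 peaks, and as many adjusted over the list alone (3 and 8 of 48 genes, Fisher's exact test, adjusted p = 0.399 and 0.434). In the authors' deposited table their most changed called peaks included a single peak within osa with 0.60 and one within HDAC4 with -0.59. Neither peak of Trl, the GAGA factor gene, was called (smallest FDR 0.491).

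Sugar metabolism, mitochondrial and receptor gene lists made no call in either direction. Carbohydrate metabolism had 4 peaks higher at 25 °C and 7 at 11 °C of 60, or 4 and 6 adjusted over the list alone (3 and 6 of 32 genes, Fisher's exact test, adjusted p = 0.893 and 0.434). The trehalose transporter gene Tret1-1 had 0.60 and the pyruvate kinase gene PyK -0.36 in the authors' deposited table. Mitochondrial energy metabolism had 4 and 0 of 37 peaks, or 3 and 0 adjusted over the list alone (3 and 0 of 29 genes, Fisher's exact test, adjusted p = 1 and 0.225), with 0.65 at Ogdh in the authors' deposited table. Steroid and neuropeptide receptors had 4 and 3 of 21 peaks, and as many adjusted over the list alone (3 genes each way of 11, Fisher's exact test, adjusted p = 0.375 and 0.297). From the authors' deposited table, the neuropeptide receptor gene sNPF-R had -0.64 and put had 1.10. The list's name does not cover all its members, as put encodes a receptor of the TGF-beta family.

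Markers of other tissues were checked because a dissected fat body can carry other cells. Muscle markers had 10 of 30 peaks higher at 25 °C and 0 at 11 °C, and as many adjusted over the list alone. On genes it was 6 of 11 for 25 °C (Fisher's exact test, adjusted p = 0.0127), a call that both other tests ended (adjusted p = 0.319 for random lists and 0.432 for matched draws). Oenocyte markers, genes of the hydrocarbon-producing cells that lie under the cuticle next to the fat body, had 8 and 0 of 20 peaks, and as many adjusted over the list alone. On genes it was 5 of 8 (Fisher's exact test, adjusted p = 0.0127), and again both other tests ended the call (adjusted p = 0.252 and 0.0528). The medians of both lists and of the fat body and immunity lists lay above those of matched random lists, at log2 fold changes of 0.22, 0.24, 0.11 and 0.10 (permutation test, adjusted p = 0.0103, 0.011, 0.0477 and 0.0066). With the decile medians subtracted all 4 still did (permutation test, adjusted p = 0.0473, 0.0205, 0.0205 and 0.0205). By the authors' deposited table, the muscle genes how and mspo had 1.44 and 1.05, and the oenocyte genes Fad2 and FASN3 1.09 and 0.92.

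The other 5 marker lists made no call in either direction. Hemocyte markers had 3 and 6 of 20 peaks, or 3 and 7 adjusted over the list alone (3 and 4 of 9 genes, Fisher's exact test, adjusted p = 0.275 and 0.0726), with -0.57 at drpr and 0.41 at crq in the authors' deposited table. Neuron and glia markers had 1 and 3 of 17 peaks, as also adjusted over the list alone (1 and 3 of 11 genes, Fisher's exact test, adjusted p = 1 and 0.297), with 0.42 at para and -0.38 at ChAT in the authors' deposited table. Ovary and germline markers had 2 and 2 of 20, as also adjusted over the list alone (1 and 2 of 12 genes, Fisher's exact test, adjusted p = 1 and 0.759), with 0.60 at AGO3 and -0.21 at exu in the authors' deposited table. Gut and Malpighian tubule markers had 2 and 2 of 14, or 2 and 4 adjusted over the list alone (2 genes each way of 9, Fisher's exact test, adjusted p = 0.483 and 0.443). By the authors' deposited table, ct had -0.88 and Amy-p 0.88. Tracheal and epidermal markers had 3 and 2 of 11, as also adjusted over the list alone (1 and 2 of 7 genes, Fisher's exact test, adjusted p = 1 and 0.399), with 0.39 at a peak 1125 bp from bnl and -0.88 at grh in the authors' deposited table.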

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

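No paired analysis was possible because the table analysed gives 1 comparison with no value per library, and for the same reason the replicate block, leaving out each replicate and another scaling of counts were not run. Motif alternatives were not run, as they need the genome sequence. Alternatives without pericentromeric windows and chromosome 4 or without tRNA peaks, the sign from concentrations, the matched peak draws and the decile subtraction were chosen after seeing the data. Of 428 recomputed values 333 kept their direction and side of the threshold, and 49 more passed in neither setting but lay on the other side of no difference.

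Counts of calls went from 1789 to 803 at an FDR under 0.001 (467 higher at 25 °C, 336 at 11 °C), to 175 with a log2 fold change of at least 1 (124 and 51) and to 1143 without the lowest of 4 concentration bins (492 at 25 °C). At an FDR under 0.01, 512 were higher at 11 °C. These counts fall by construction. The median of all peaks was -0.0176 without that bin. For the rest the cause was not tested. Gene ends, 25 °C against 11 °C, passed with odds ratios of 0.794 (1000 bp) and 0.776 (protein-coding genes). The distance difference between 25 °C and 11 °C peaks lost its call at an FDR under 0.01 (457 bp) and without pericentromeric windows and chromosome 4 (172 bp), and within gene-end peaks was -3 bp. Concentration of 11 °C peaks against the rest passed at an FDR under 0.01 (-0.15).

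Gene lists lost calls as follows, with odds ratios, or ratios to random lists or draws. By nearest gene end, ecdysone 2.80, heat shock 2.46, clock 5.10, fat body 5.13 and oenocyte 12.3. With gene-end peaks alone, ecdysone 2.10, heat shock 6.44, clock 1.44, fat body 5.79, oenocyte 8.68 and muscle 3.85. Against matched random lists, ecdysone 1.13, heat shock 2.56, clock 1.51, fat body 1.90, oenocyte 2.19 and muscle 1.76. Against matched draws, ecdysone 1.25, immunity 1.97, heat shock 1.94, clock 1.11, oenocyte 2.87 and muscle 1.56. At an FDR under 0.01, ecdysone 3.63, heat shock 3.39 and fat body 4.07, while ecdysone (6.003) and hemocyte (10.4) passed for 11 °C. With decile medians subtracted, the insulin (-0.0575) and cell cycle (-0.0240) medians no longer passed. For the 147 named peaks, 233 of 294 calls or non-calls were the same under the stricter FDR limits and 61 calls were lost. The non-calls among the 233 stay the same by construction, so only the lost calls tell of stability. An FDR under 0.1 and centring can by construction lose none. The depth of the libraries is unknown, and the 2018 peaks of the lowest bin, median log2 concentration 6.04, limit the balance of directions, which also moved with a minimum log2 fold change of 1.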

Other observations

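The tests of gene types, symbol families and chromosome windows, the draws for muscle and oenocyte peaks and the test of the concentration trend as whole cause were chosen after the result was seen, as was the use of the planned random lists to weigh explanations for those markers, and the single genes named here were picked after their values were seen. Peaks at tRNA genes stood out among 40 symbol prefixes that were looked through. Tested over the 38 of them that had a gene with a peak, in both directions (76 tests on genes), tRNA genes passed for 25 °C and against 11 °C (Fisher's exact test, adjusted p = 3.23e-15 and 2.58e-07) and lncRNA genes for 11 °C (66 of 378 genes, adjusted p = 0.00897). Several tRNA genes can share a peak, so the test on peaks is the sounder one. Of the 113 peaks within 500 bp of a tRNA gene, 41 were higher at 25 °C (36.3%, 95% exact interval 27.4 to 45.9) and 1 at 11 °C, against 11.8% of other peaks for 25 °C (Fisher's exact test, adjusted p = 3.45e-10 over 14 tests). In the authors' deposited table the most changed were a peak at tRNA:Val-CAC-2-5 (3R, 19671675 to 19672075) with a log2 fold change of 1.46 and one at tRNA:Lys-CTT-1-7 and tRNA:Lys-CTT-1-8 with 1.25. Of 334 peaks at lncRNA genes 57 were higher at 11 °C (17.1%, 95% exact interval 13.2 to 21.5), against 9.71% of other peaks (Fisher's exact test, adjusted p = 0.000364). No draws matched on location and concentration were made for the lncRNA peaks.

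Cytochrome P450 genes, oxidases of hormones, fatty acids and toxins, had 15 of 60 genes with a peak higher at 25 °C and 1 with one higher at 11 °C, which did not pass over the 76 tests (Fisher's exact test, adjusted p = 0.121 both). In the authors' deposited table the largest were Cyp9h1 with 0.91, in a peak shared with Or49b, and Cyp4d1 with 0.87, and the one higher at 11 °C was Cyp4e3 with -0.85. SNF4Agamma, the regulatory subunit of the energy sensor AMPK, had the most peaks higher at 25 °C of any gene, 7 of 13, with 1 higher at 11 °C. Pericentromeric windows held 5.20% of the peaks higher at 25 °C and 2.72% of those higher at 11 °C (Fisher's exact test, adjusted p = 0.0124). None of the 7 peaks on the Y chromosome was called (smallest FDR 0.0999), and these flies were female.

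For the tRNA peaks, low read concentration is argued against, as their median log2 concentration was 7.94, against 7.46 for other gene-end peaks. Draws of other peaks with the same location class and concentration held a mean of 7.21 peaks higher at 25 °C, against 41. A few gene clusters are argued against too: of 86 tRNA peaks with no other within 10 kb, 36% were higher at 25 °C (95% exact interval 26 to 47.1). Other gene-end peaks had 7.47%. A tRNA peak is a gene-end peak by its tRNA gene's own ends, even inside a longer gene. Both contrasts thus use the location class with the lowest share higher at 25 °C, and their size may be too large. Reads shared between identical tRNA copies remain open, since the 10 peaks at tRNA genes with a single copy gave 20% with an interval of 2.52 to 55.6 that holds both shares; the rule for reading it was widened to intervals that hold both after the value was seen. A change at every RNA polymerase III gene cannot be told from one at tRNA genes, as 0 of only 3 other such peaks was higher at 25 °C. A difference in tRNA gene accessibility between temperatures therefore stays a hypothesis, and the effect of S-methoprene on it is untested.

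Peaks higher at 25 °C had a lower read concentration than those higher at 11 °C, by 0.80 on the log2 scale. Pericentromeric and chromosome 4 peaks do not account for it, as the difference without them was -0.78. A weaker signal over background in the 25 °C libraries is a candidate explanation: over all peaks the median log2 fold change was 0.104 higher in the lowest than in the highest of 4 concentration bins (bootstrap 95% interval 0.0935 to 0.115), as such a difference would give. With the decile medians subtracted, 88.8% of the 981 peaks were still called (95% exact interval 86.6 to 90.7). The p-values were recomputed from a standard error taken approximately from the fitted fold change and its p. This test replaced 2 earlier forms with a bar that every called peak met before the subtraction. The medians of the lowest and highest deciles were only 0.0959 and -0.0744, and the smallest log2 fold change called for 25 °C was 0.170. Most calls were thus likely to stay, so the test cannot show whether the trend is the whole cause of the calls. The subtraction with recomputed p-values took the difference in concentration to -0.21 (permutation test, p = 0.00028), so most of that difference went with the trend. A technical difference and a true opening of weak peaks at 25 °C stay open as its source.

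Muscle and oenocyte marker lists had medians above matched random lists in favour of 25 °C. A lower share of fat body nuclei in the 25 °C libraries would by itself lower the fat body list, whose own median lay at percentile 99.39. Of its 14 genes with a peak, 6 had one higher at 25 °C and 3 one higher at 11 °C. Changes within fat body cells can also move this list, and it cannot separate such changes from a share of nuclei. A lower share of fat body nuclei therefore stays open. For the medians, the random lists matched on peaks per gene cannot weigh many peaks per gene as an explanation. The medians lay at percentiles 99.94 and 99.91 of such lists (permutation test, adjusted p = 0.0103 and 0.011 over 22 lists), but these same percentiles define the pattern. For the gene counts many peaks per gene stay open, as matching on them ended those calls (permutation test, adjusted p = 0.319 and 0.252). Location and concentration fit the number of muscle peaks higher at 25 °C, 10 against 6.25 in matched draws (ratio 1.56), but not that of oenocyte peaks, 8 against 2.46 (ratio 2.87), though over the 44 tests of lists this has adjusted p = 0.0528 (permutation test). More muscle or oenocyte nuclei in the 25 °C dissections, or a change within these cells or in the fat body at these genes, may each give this, and the table holds no value that separates them.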
